A study of Homo sapiens with 4 samples.

How the data were processed

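Total RNA from the human cell line BLaER1 was sequenced in 4 libraries, 2 from undifferentiated and 2 from differentiated cells. BLaER1 is a B cell leukaemia line that carries the transcription factor C/EBPα joined to the hormone-binding domain of the oestrogen receptor, and it can be turned into cells with macrophage features. Per the labels' protocols, differentiated cells had spent 5 to 6 days in medium with IL-3, M-CSF and 100 nM oestradiol, with a concentration of 10 ng/ml written once, before IL-3. Whether it also holds for M-CSF is not certain. RNA was isolated with Trizol and a column kit, and stranded libraries were made from total RNA with the NuGEN Encore Complete kit, per the same protocols.

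The deposited values are TPM, an abundance normalized for gene length, in 1 table with 1 column per library and 58302 gene rows identified by Ensembl gene ID and symbol. Per the submitters' processing notes, the authors used Trimmomatic, STAR and RSEM, which name a read trimmer, an aligner and an abundance estimator. Their versions, settings, genome build and annotation are not given in the sources used here, so no coordinates are given. TPM divides each gene's estimated reads by its length and scales every library to the same sum. It therefore keeps no sequencing depth, and no counting error or detection limit could be computed. A share taken by an abundant RNA lowers the TPM of every other gene in that library. RSEM distributes reads that match several genes, so values of near-identical gene copies are uncertain.

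Samples were grouped by the stage in their labels, and columns were assigned to samples by the sample titles. No column of values was left out. Gene types, and the GC content and length of protein-coding transcripts, came from GENCODE release 29, in which 58039 of the 58302 IDs were found. This release need not be the authors' annotation.

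Genes with at least 1 TPM in at least 2 of the 4 libraries were tested, which left 10180. A gene expressed at 1 stage alone passes this filter through that stage's libraries. In lists of genes little expressed before differentiation, the share of tested members called higher therefore depends partly on this filter. List members below it are in no count of tested members. Values were transformed to log2(TPM + 1), and stages were compared with limma 3.58.1 in R 4.3.3 (a linear model with moderated variances and a mean-variance trend, two-sided). Genes with a Benjamini-Hochberg adjusted p below 0.05 over all tested genes are referred to as called. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low TPM. No fold is given for a gene listed at 0 in both libraries of a stage. The fit had 2 residual degrees of freedom and 10.9 prior degrees of freedom. An exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333, so single genes were judged by the model alone.

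Before the data were examined, 25 gene lists with a set test, 9 lists without one (other cell types, RNA classes and housekeeping genes), 10 anchor genes and the processing alternatives were fixed. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 25 lists, together with the number of members called over all genes and the number adjusted over the list alone. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera uses the 2 residual degrees of freedom, and all 19 lists called with the preset correlation lost their call. Fry, which tests whether a list's genes move on balance in a single direction and does not compare them with other genes, called 14 lists.

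The genes named are the anchor genes, up to 2 called members of each tested list with the largest change in its main direction and 1 in the other direction, the 8 largest rises and 8 largest falls with non-overlapping libraries, and the 2 most abundant members of each list without a set test. Some genes that this rule selects are not reported here. Any other gene was chosen after its values were seen.

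The procedure was tested on simulated data for the comparison of differentiated with undifferentiated cells, with 10180 genes and 20 data sets per scenario. With 200 changed genes it recovered 4.85% of those changed by a log2 difference of 1, 70.4% at 2 and 99.8% at 4, and 3.5% of calls were false. With 4000 changed genes these shares were 47.6%, 97.5% and 100%, with 2.94% false calls. Gene variances were drawn from the distribution that the model itself had fitted. The simulated libraries held none of the shifts and GC trends between whole libraries that the real data show. The shares of false calls therefore hold under the model's own assumptions and do not measure errors among the real calls. A changed list was found in 20 of 20 data sets, and 0 of 500 unchanged lists were called by camera with the preset correlation. Simulated genes varied independently, whereas the correlation estimated in the real lists as deposited ran from 0.051 for histones to 0.721 for cell cycle genes. After median-of-ratios scaling it was 0.632 for histones and 0.015 for cell cycle genes, so these estimates depend on the scaling. The simulation therefore cannot show how often unchanged lists of correlated genes are called.

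Alternatives comprised pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrial genes, small structural RNAs and the 50 most abundant genes, eBayes without a trend or robust, the replicate number as a block, a test against a log2 fold change of 1, and leaving out each library in turn. Rescaling over protein-coding genes alone, with and without median-of-ratios scaling, removal of GC or length trends, and camera with an estimated correlation after median-of-ratios scaling were added after the data had been seen.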

Results

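Gene expression was measured by RNA sequencing of total RNA in 2 libraries of undifferentiated and 2 libraries of differentiated BLaER1 cells, a human B cell leukaemia line. The labels describe the comparison as expression before and after 5 to 6 days with IL-3, M-CSF and oestradiol. Values were the authors' TPM, which carry no sequencing depth, so the depth of each library is unknown. Nothing in the labels says that the libraries of a stage came from separate cultures, and the p-values therefore measure only the spread between these libraries, which may be technical.

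Abundant structural RNAs made up most of every library. RN7SK, the small nuclear RNA that restrains transcription elongation, took 20.9% and 23.5% of the summed TPM in the differentiated libraries and 35.5% and 41.7% in the undifferentiated libraries. Protein-coding genes took 12.2% and 13.5% after differentiation against 23.0% and 15.6% before it. Small nucleolar RNAs took 10.4% and 9.01% after differentiation and 4.62% and 6.12% before it. RN7SK itself averaged 222100 ± 18600 TPM in differentiated and 385900 ± 43870 TPM in undifferentiated cells (SD, n = 2). The log2 difference was -0.80 (adjusted p = 0.00798). Quantile normalization gave 0.00 by construction, because RN7SK was the most abundant gene in every library, so it cannot decide on this gene. RN7SK was not called after median-of-ratios scaling (adjusted p = 0.528) or with eBayes without a trend (adjusted p = 0.0741). Its call was also lost with any single library left out (adjusted p from 0.144 without differentiated replicate 2 and 0.19 without differentiated replicate 1 to 0.263 and 0.342 without undifferentiated replicates 1 and 2).

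**Figure D1:**
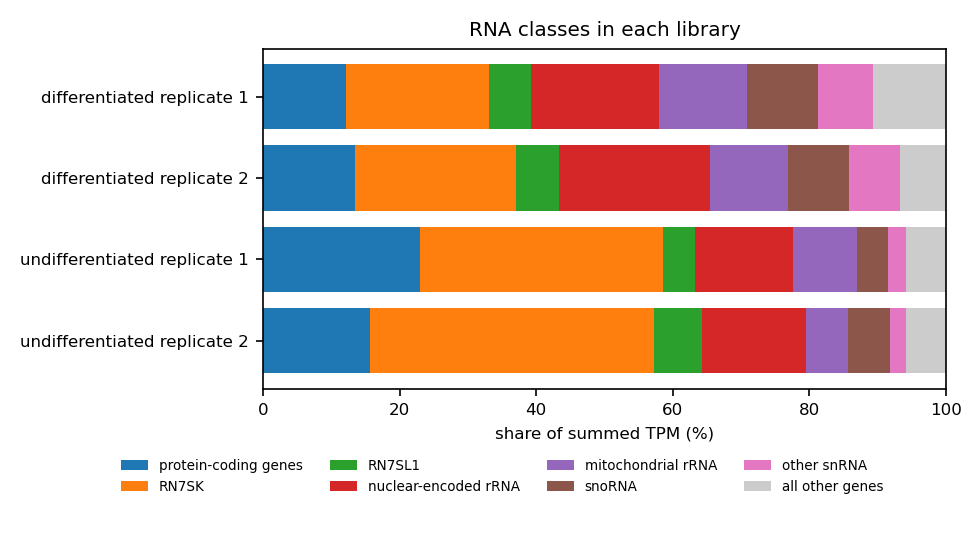
Share of summed TPM (%, horizontal axis) taken by RNA classes in each of the 4 libraries (rows), with mitochondrially encoded mRNAs among the protein-coding genes. RN7SK took 35.5% and 41.7% of the undifferentiated and 20.9% and 23.5% of the differentiated libraries.

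Libraries of the same stage resembled each other more than libraries of different stages. Across genes, which are not independent replicates, log2(TPM + 1) values correlated with r = 0.965 between the differentiated and r = 0.947 between the undifferentiated libraries, and with r = 0.575 to 0.627 between stages. Undifferentiated replicate 1 lay above replicate 2 by a median log2 difference of 0.505, whereas the median difference between the differentiated libraries was -0.063. At least 1 TPM was listed for 9268 and 9220 genes in the differentiated and for 9641 and 8142 genes in the undifferentiated libraries.

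Differentiation was accompanied by a change in a large part of the expressed genes. Of 10180 genes tested, 4216 were called, 1890 of them higher and 2326 lower in differentiated cells (limma, Benjamini-Hochberg adjusted), and 3807 of these differed by at least 1 on the log2 scale. The libraries of the stages did not overlap for 7124 tested genes (70%). The share would be 33.3% if all libraries were interchangeable. Whole libraries were shifted against each other and genes share such shifts, so the 2 shares are not a test. The median log2 difference over all tested genes was -0.14, and it was 0.04 after median-of-ratios scaling, -0.08 after quantile normalization and 0.37 over protein-coding genes rescaled alone. Medians under other scalings are therefore given for some lists. Those of other lists moved as well. Over protein-coding genes the median went from 1.10 to 2.53 for STAT5 targets and from -2.43 to -3.80 for pre-B genes. Of the calls, 44.8% were higher as deposited and, over the same 10180 genes, 52.4% after median-of-ratios scaling and 46.3% after quantile normalization. The share was 58.7% (3616 higher, 2546 lower) after rescaling without the most abundant RNAs and 65.6% (4102 higher, 2153 lower) after rescaling over protein-coding genes, which also changed the genes tested (14923 and 11945). Without differentiated replicate 1 the fit called 949 genes higher and 344 lower, and without differentiated replicate 2 it called 934 and 337. It called 2714 higher and 2097 lower without undifferentiated replicate 1, and 1834 and 3818 without undifferentiated replicate 2.

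The largest called difference among protein-coding genes was that of SPP1, which encodes the secreted matrix protein osteopontin. It was listed at 2563 and 2504 TPM in the differentiated libraries and at 0 in both undifferentiated libraries (adjusted p = 4.45e-10). The other 7 of the 8 largest called differences in this direction belonged to small RNAs or their copies, each listed at 0 in both undifferentiated libraries. They were the small nucleolar RNA SNORD89 (17776 and 11928 TPM), the Y RNA RNY1 (20650 and 7700 TPM), the spliceosomal RNAs RNU5B-1 (6502 and 3298 TPM), RNU5A-1 (5370 and 1989 TPM) and RNU5E-1 (1959 and 714 TPM), and the 5S rRNA pseudogenes RNA5SP226 (2610 and 842 TPM) and RNA5SP389 (2262 and 676 TPM). Among the largest differences in the other direction, the U1 small nuclear RNA copies RNU1-1, RNU1-2, RNU1-4, RNVU1-18 and 2 genes with the symbol U1 carried identical values of 2314 and 1235 TPM in the undifferentiated libraries and 0 in both differentiated libraries. Reads of such copies cannot be assigned to single genes. An exact 0 can also be a failed estimate, SNORD89 and RNY1 included. U1 and U5 RNAs are used by every cell, and RNU2-1 and RNU6-1, likewise parts of the spliceosome, were listed at 0 TPM in all 4 libraries. These small RNAs are therefore given only as listed, and no change is read from them. BCYRN1, a small cytoplasmic RNA with many related repeats, averaged 3.79 ± 3.30 TPM after and 357 ± 34.5 TPM before differentiation (SD, n = 2). The immunoglobulin variable gene IGHV2-70 averaged 6.11 ± 0.226 and 482 ± 62.6 TPM, a log2 difference of -6.08 ± 0.35 (SE, adjusted p = 8.93e-08).

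Genes of the pre-B stage were lower after differentiation. DNTT, the polymerase that adds nucleotides at V(D)J junctions, averaged 1.76 ± 0.106 TPM in differentiated and 148 ± 56.7 TPM in undifferentiated cells (SD, n = 2), a log2 difference of -5.70 ± 0.40 (SE, adjusted p = 4.66e-07). IGLL1, a surrogate light chain component, averaged 0.70 ± 0.311 and 62.8 ± 31.3 TPM (log2 difference -5.15, adjusted p = 2.32e-06). Of 18 tested pre-B receptor and V(D)J recombination genes, 0 were higher, 14 lower and 4 not called (14 lower adjusted over the list alone), with a median log2 difference of -2.43 (camera adjusted p = 7.86e-08, adjusted p = 0.401 with an estimated correlation).

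Of 23 tested B cell transcription factors, 13 were lower, 4 higher and 6 not called (14 lower and 4 higher adjusted over the list alone). MYB, a regulator of progenitor growth, averaged 2.60 ± 0.233 TPM after and 83.9 ± 39.0 TPM before differentiation (adjusted p = 4.65e-06). LEF1 averaged 5.02 ± 0.948 and 122 ± 52.2 TPM (adjusted p = 5.6e-06; SD, n = 2). PAX5 (ENSG00000196092), the factor that maintains B cell identity, averaged 0.585 ± 0.00707 and 10.5 ± 3.98 TPM, a log2 difference of -2.81 ± 0.40 (SE, adjusted p = 0.000106). IRF8, which also acts in monocytes, was higher at 22.0 ± 1.69 against 1.75 ± 0.948 TPM (adjusted p = 5.38e-05). The list's median was -1.32 (camera adjusted p = 0.00159, adjusted p = 0.628 with an estimated correlation), and the list was not called among genes of at least 5 TPM (adjusted p = 0.086). Without differentiated replicate 1 or 2 the adjusted p was 0.0698 and 0.0694 for PAX5 and 0.0523 and 0.059 for IRF8.

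B cell receptor and surface genes went both ways, with 13 of 24 tested members (34 in the list) lower, 8 higher and 3 not called (13 lower and 9 higher adjusted over the list alone). CD24 averaged 2.40 ± 1.37 TPM after and 93.9 ± 25.4 TPM before differentiation (adjusted p = 2.82e-06), and the IL-7 receptor gene IL7R 7.49 ± 0.933 and 179 ± 92.1 TPM (adjusted p = 6.92e-06; SD, n = 2). The kinase gene LYN, which is used in B cells and myeloid cells, was higher at 27.0 ± 3.46 against 2.68 ± 1.48 TPM (adjusted p = 8.43e-05). The list was not called (camera adjusted p = 0.296, adjusted p = 0.893 with an estimated correlation), except without a filter on low values (adjusted p = 0.0192). The adjusted p for LYN was 0.0546 and 0.0676 without differentiated replicate 1 or 2.

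Macrophage and monocyte surface receptors were higher in differentiated cells for nearly all tested members of the list. Of 47 tested members (56 in the list), 44 were higher, 0 lower and 3 not called (45 higher adjusted over the list alone), with a median log2 difference of 3.61 (camera adjusted p = 7.62e-30, adjusted p = 0.397 with an estimated correlation). Apart from CSF1R, the members called higher averaged below 1 TPM before differentiation. They passed the filter on low values through the differentiated libraries, so the share called higher depends partly on this filter. The 3 members not called, CSF2RB, LILRB4 and ADGRE5, averaged 1.755, 2.265 and 3.19 TPM in undifferentiated cells. CD68, a lysosomal membrane protein of macrophages, averaged 207 ± 14.4 TPM after and 0.435 ± 0.233 TPM before differentiation (SD, n = 2), a log2 difference of 7.19 ± 0.37 (SE, adjusted p = 3.63e-08). CD14 (ENSG00000170458), the co-receptor for lipopolysaccharide, averaged 111 ± 15.2 and 0.095 ± 0.0495 TPM (log2 difference 6.67, adjusted p = 7.59e-08). The integrin gene ITGAM (ENSG00000169896) averaged 17.9 ± 1.55 and 0.015 ± 0.00707 TPM (log2 difference 4.22, adjusted p = 3.72e-06). CSF1R (ENSG00000182578), the M-CSF receptor, was already listed at 6.42 and 5.84 TPM before differentiation and averaged 116 ± 17 TPM after it (log2 difference 4.03, adjusted p = 3.91e-06).

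**Figure D2:**
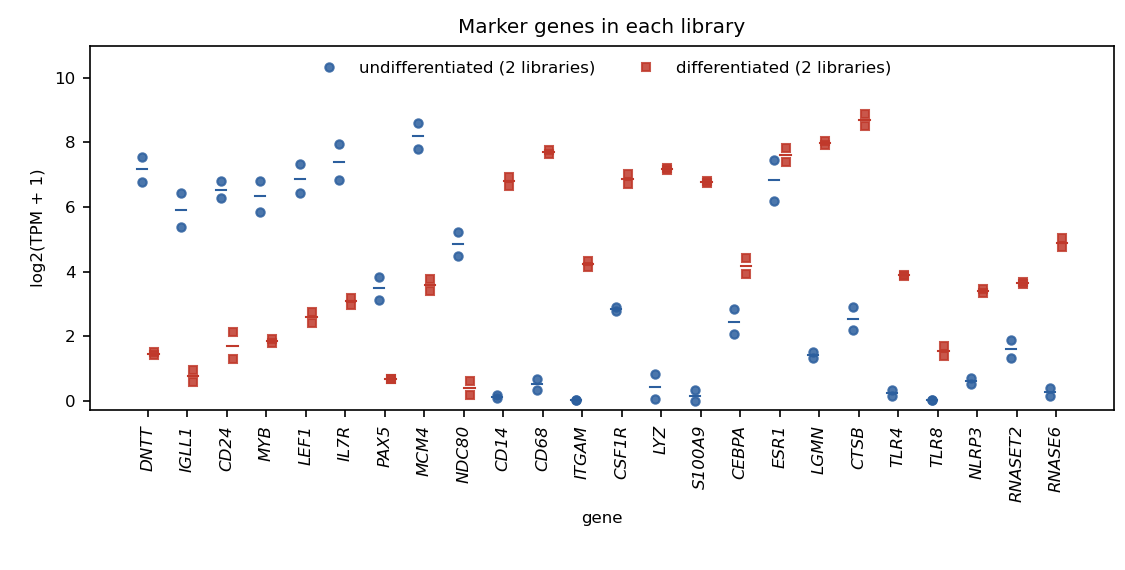
Log2(TPM + 1) of 24 named genes (horizontal axis) in each library, circles for the 2 undifferentiated and squares for the 2 differentiated libraries, with short lines at their means. B lineage and cell cycle genes at the left lie higher in undifferentiated cells (DNTT 148 against 1.76 TPM), macrophage and innate genes at the right higher in differentiated cells (CD68 207 against 0.435 TPM), and ESR1 was not called as deposited.

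Myeloid transcription factors that passed the filter on low values were higher as a group. Of 30 tested members (38 in the list), 26 were higher, 1 lower and 3 not called (26 higher and 1 lower adjusted over the list alone). ID2, an inhibitor of E proteins, averaged 98.7 ± 4.58 TPM after and 1.70 ± 0.0707 TPM before differentiation (adjusted p = 5.2e-07; SD, n = 2). CEBPA (ENSG00000245848) averaged 17.3 ± 4.37 and 4.66 ± 2.09 TPM, a log2 difference of 1.72 ± 0.41 (SE, adjusted p = 0.0046, but 0.0984 without a filter on low values and 0.259 against a log2 fold change of 1). NFIL3 was lower at 1.74 ± 0.156 against 7.54 ± 3.96 TPM (adjusted p = 0.00988). The list's median was 1.84 (camera adjusted p = 2.6e-12, adjusted p = 0.397 with an estimated correlation). ESR1 (ENSG00000091831) averaged 196 ± 42.9 and 124 ± 73.8 TPM and was not called as deposited (adjusted p = 0.164), but was called higher after median-of-ratios scaling (adjusted p = 0.0314) and quantile normalization (adjusted p = 0.0215). It was also called higher over protein-coding genes, rescaled alone (adjusted p = 0.00513) or with median-of-ratios scaling (adjusted p = 0.0177), and with the GC or length trend removed (adjusted p = 0.00876 and 0.00288). Gene-level values of CEBPA and ESR1 cannot separate the endogenous transcripts from those of the introduced fusion. Left out in turn, differentiated replicates 1 and 2 gave an adjusted p of 0.146 and 0.264 for CEBPA and 0.289 and 0.26 for NFIL3, and ESR1 was called without undifferentiated replicate 1 (adjusted p = 0.0159).

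Effector and degradative genes of phagocytes that passed the filter on low values were mostly higher. Of 35 granule and antimicrobial proteins, 20 were below 1 TPM in all 4 libraries and 15 were tested. Of these 15, 12 were higher, 0 lower and 3 not called (12 higher adjusted over the list alone). The list's median log2 difference was 3.95 (camera adjusted p = 1.68e-10, adjusted p = 0.397 with an estimated correlation). Lysozyme (LYZ) averaged 144 ± 5.33 TPM after and 0.405 ± 0.530 TPM before differentiation (SD, n = 2, adjusted p = 1.04e-07). S100A9, a calcium-binding protein of myeloid cells, was listed at 106 and 111 TPM after and at 0.25 and 0 TPM before it. Of 46 tested lysosomal proteins, 38 were higher, 0 lower and 8 not called (38 higher adjusted over the list alone). The median log2 difference of the 46 genes was 1.69 (camera adjusted p = 4.79e-14, adjusted p = 0.397 with an estimated correlation). The proteases LGMN and CTSB averaged 252 ± 15.1 and 417 ± 80.2 TPM after and 1.68 ± 0.233 and 5.00 ± 1.98 TPM before differentiation, log2 differences of 6.57 and 6.15. Among 12 tested ribonucleases and deoxyribonucleases (23 in the list), 10 were higher and 2 lower (the same counts adjusted over the list alone). The nuclease list had a median log2 difference of 1.70 (camera adjusted p = 0.000111, adjusted p = 0.397 with an estimated correlation). RNASE1 was listed at 74.7 and 89.9 TPM in differentiated and at 0 in both undifferentiated libraries, and RNASE6 averaged 28.7 ± 4.07 and 0.205 ± 0.149 TPM. RNASET2 (ENSG00000026297), a lysosomal ribonuclease that processes RNA for TLR8, averaged 11.5 ± 0.325 and 2.11 ± 0.834 TPM, a log2 difference of 2.03 ± 0.39 (SE, adjusted p = 0.00105, but 0.0733 against a log2 fold change of 1). The exoribonuclease gene ERI1 was lower at 1.06 ± 0.113 against 3.29 ± 0.523 TPM (adjusted p = 0.0225). Without differentiated replicate 1 or 2 the adjusted p was 0.136 and 0.145 for RNASET2 and 0.353 and 0.301 for ERI1. The ERI1 call was also lost with the GC trend removed (adjusted p = 0.11) and after rescaling over protein-coding genes (adjusted p = 0.0565).

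Innate sensing genes that passed the filter on low values were mostly higher. Of 23 tested Toll-like receptors and adaptors (30 in the list), 14 were higher, 0 lower and 9 not called (14 higher and 1 lower adjusted over the list alone). Apart from UNC93B1, the members called higher averaged below 1 TPM before differentiation, so the share called higher depends partly on this filter. The 9 members not called averaged above 1 TPM before it. Over the list the median log2 difference was 1.33 (camera adjusted p = 6.56e-06, adjusted p = 0.534 with an estimated correlation). TLR4, the lipopolysaccharide receptor, averaged 13.8 ± 0.184 TPM after and 0.185 ± 0.106 TPM before differentiation (adjusted p = 1.09e-05), and TLR1 averaged 16 ± 1.41 and 0.805 ± 0.389 TPM (adjusted p = 3.2e-05; SD, n = 2). TLR8 (ENSG00000101916), a sensor of RNA fragments, was low at 1.92 ± 0.410 TPM after differentiation and listed at 0.01 TPM in both undifferentiated libraries (adjusted p = 7.86e-05). The TLR8 call was lost without a filter on low values (adjusted p = 0.059) and in the test against a log2 fold change of 1 (adjusted p = 0.0859). Of 23 tested inflammasome genes (30 in the list), 18 were higher, 1 lower and 4 not called (19 higher and 2 lower adjusted over the list alone). The list's median log2 difference was 1.81 (camera adjusted p = 2.01e-07, adjusted p = 0.397 with an estimated correlation). NLRP3 (ENSG00000162711), an inflammasome sensor, averaged 9.57 ± 0.672 and 0.535 ± 0.134 TPM (log2 difference 2.78, adjusted p = 6.93e-05). The interleukin-1 receptor antagonist gene IL1RN averaged 12.5 ± 1.93 and 0.11 ± 0.113 TPM, and PSTPIP1 13.9 ± 3.83 and 0.34 ± 0.141 TPM. DFNA5, the pyroptosis gene also called GSDME, was lower at 0.20 ± 0.212 against 1.58 ± 0.382 TPM (adjusted p = 0.00147, and 0.0871 without differentiated replicate 2).

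Cytosolic nucleic acid sensing genes went both ways, with 8 of 21 tested members (26 in the list) higher, 4 lower and 9 not called (9 higher and 4 lower adjusted over the list alone). SAMHD1, which cleaves nucleotides, averaged 5.94 ± 0.149 TPM after and 0.115 ± 0.106 TPM before differentiation, and OAS1 averaged 6.77 ± 0.785 and 0.285 ± 0.219 TPM. RNASEH2B, a subunit of the enzyme that cuts RNA in RNA-DNA hybrids, was lower at 1.41 ± 0.339 against 9.37 ± 4.42 TPM (adjusted p = 0.00166; SD, n = 2). The list's median was 0.53 and its camera adjusted p 0.0331, with adjusted p = 0.71 with an estimated correlation. This call was lost without undifferentiated replicate 1 (adjusted p = 0.0575), with the GC trend removed (adjusted p = 0.0582) and after rescaling over protein-coding genes (adjusted p = 0.0568). RNASEH2B was not called without differentiated replicate 1 or 2 (adjusted p = 0.135 and 0.18).

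Cytokines and interferon-stimulated genes that passed the filter were higher as groups. Of 37 cytokines and chemokines, 19 were below 1 TPM in all 4 libraries and 18 were tested. Of these 18, 17 were higher, 0 lower and 1 not called (17 higher adjusted over the list alone). The median log2 difference of these genes was 2.48 (camera adjusted p = 6.87e-12, adjusted p = 0.397 with an estimated correlation). The monocyte attractant CCL2 was listed at 27.5 and 34.8 TPM after and at 0 and 0.32 TPM before differentiation. Of 28 tested interferon-stimulated genes (38 in the list), 16 were higher, 1 lower and 11 not called (17 higher and 1 lower adjusted over the list alone). The interferon-stimulated list had a median log2 difference of 0.99 (camera adjusted p = 3.87e-06, adjusted p = 0.397 with an estimated correlation). GBP2 averaged 6.60 ± 0.460 and 0.065 ± 0.0354 TPM, and IFIT2 6.64 ± 0.134 and 0.175 ± 0.00707 TPM (SD, n = 2). HERC5 was lower at 0.505 ± 0.0495 against 1.63 ± 0.834 TPM (adjusted p = 0.0339). The HERC5 call was lost with the GC trend removed (adjusted p = 0.345), with eBayes without a trend (adjusted p = 0.108), with a pseudocount of 5 (adjusted p = 0.0568) and after rescaling without abundant RNAs or over protein-coding genes (adjusted p = 0.0615 and 0.0621). It was also lost without differentiated replicate 1 or 2 or undifferentiated replicate 1 (adjusted p = 0.273, 0.225 and 0.0781).

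Antigen presentation genes were examined by class. Of 15 tested MHC class II genes, 12 were higher, 0 lower and 3 not called (12 higher and 1 lower adjusted over the list alone). Over the list the median log2 difference was 1.95 (camera adjusted p = 4.77e-06, adjusted p = 0.397 with an estimated correlation). HLA-DRB1 averaged 30.3 ± 6.87 TPM after and 1.04 ± 0.587 TPM before differentiation and HLA-DRB5 28.9 ± 0.856 and 1.32 ± 0.615 TPM (SD, n = 2). Both are uncertain because these genes share reads. Of 19 tested MHC class I and antigen processing genes, 6 were higher, 5 lower and 8 not called (7 higher and 5 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.454, adjusted p = 0.893 with an estimated correlation). HLA-E averaged 59.6 ± 11.9 and 8.41 ± 2.48 TPM and HLA-C 48.6 ± 7.56 and 12.5 ± 2.91 TPM. The proteasome activator gene PSME2 was lower at 9.19 ± 2.67 against 46.6 ± 6.65 TPM. The difference between the lists was not tested. Without differentiated replicate 1 the adjusted p was 0.0943 for HLA-C and 0.0886 for PSME2, and without differentiated replicate 2 it was 0.136 for HLA-C and 0.064 for HLA-E.

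Lipid handling genes that passed the filter on low values were higher as a group. Of 18 tested members (30 in the list), 13 were higher, 2 lower and 3 not called (13 higher and 2 lower adjusted over the list alone). The list's median log2 difference was 2.05 (camera adjusted p = 4.97e-06, adjusted p = 0.397 with an estimated correlation). The scavenger receptor genes CD36 and OLR1 were listed at 11.5 and 12.5 TPM and at 14.1 and 13.8 TPM after differentiation, against 0.16 and 0 TPM and 0.25 and 0.23 TPM before it. The fatty acid carrier gene FABP5 was lower at 6.68 ± 2.84 against 35.2 ± 8.50 TPM (SD, n = 2, adjusted p = 0.000617). Of 21 tested cholesterol synthesis genes, 0 were higher, 8 lower and 13 not called (8 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.112, adjusted p = 0.763 with an estimated correlation) except without a filter on low values (adjusted p = 0.00184). HMGCS1 was lower at 3.65 ± 0.509 against 12.1 ± 6.59 TPM. The adjusted p without differentiated replicate 1 or 2 was 0.0522 and 0.111 for FABP5 and 0.351 and 0.279 for HMGCS1.

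Proliferation genes were lower in differentiated cells. Of 59 tested cell cycle genes, 58 were lower, 0 higher and 1 not called (58 lower adjusted over the list alone), with a median log2 difference of -2.75 (camera adjusted p = 7.12e-23, adjusted p = 0.397 with an estimated correlation). MCM4, a subunit of the replicative helicase, averaged 11.1 ± 2.21 TPM after and 304 ± 118 TPM before differentiation (SD, n = 2), a log2 difference of -4.60 ± 0.39 (SE, adjusted p = 2.51e-06). The kinetochore gene NDC80 averaged 0.33 ± 0.297 and 28.9 ± 10.7 TPM (log2 difference -4.46, adjusted p = 5.02e-06). Of 41 tested core and linker histone genes of the replication-dependent clusters, 39 were lower, 0 higher and 2 not called (39 lower adjusted over the list alone). The median log2 difference of the histone genes was -3.04 (camera adjusted p = 1.15e-17, adjusted p = 0.397 with an estimated correlation). HIST1H2BM averaged 9.94 ± 0.233 and 427 ± 14.6 TPM and HIST1H2BL 16.9 ± 0 and 559 ± 113 TPM, and near-identical histone genes share reads.

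**Figure D3:**
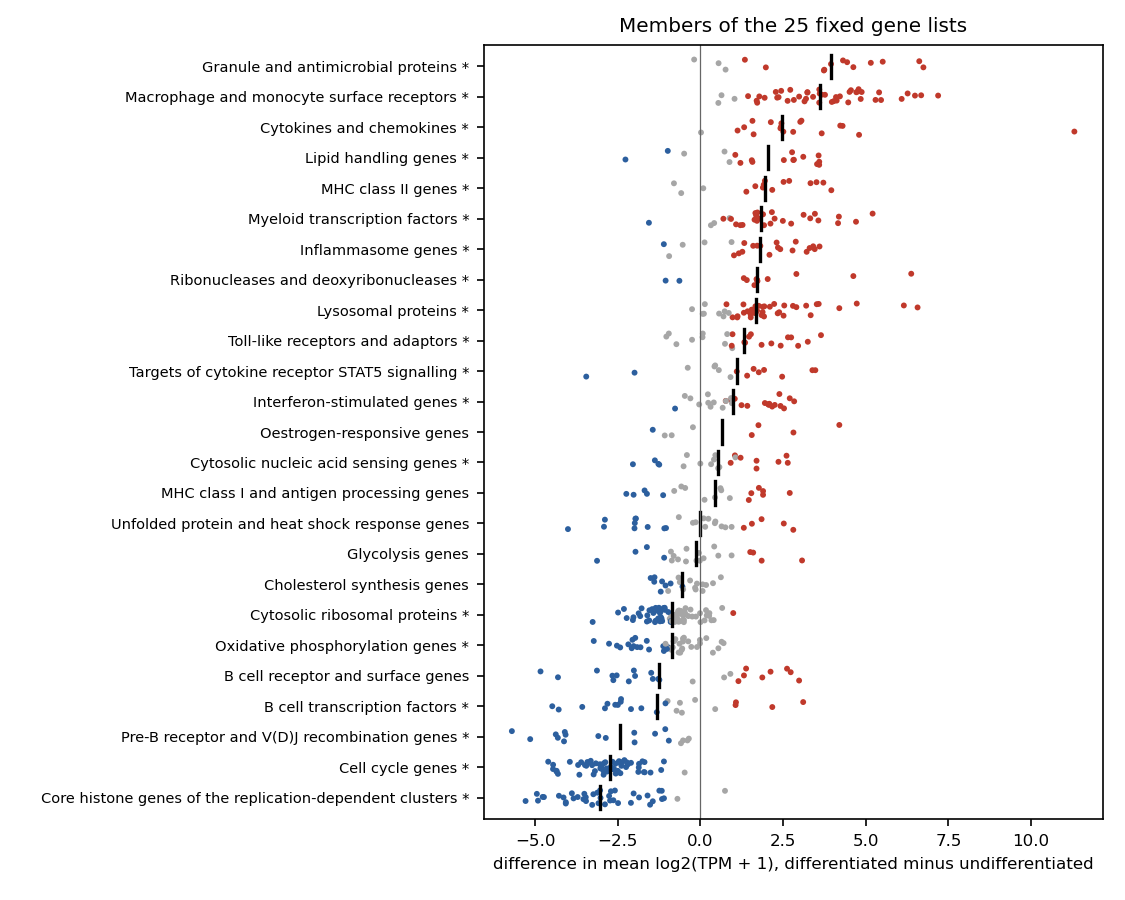
Difference in mean log2(TPM + 1), differentiated minus undifferentiated (horizontal axis), of each tested member (points) of the 25 fixed lists (rows), with 2 libraries per stage. Red and blue points are members called higher and lower, grey points were not called, black bars are medians, and asterisks mark the 19 lists with a camera adjusted p below 0.05. Medians run from -3.04 for the list labelled core histones, which also holds linker histones, to 3.95 for granule proteins. Those of glycolysis and of the unfolded protein and heat shock response turn positive when rescaled over protein-coding genes (0.43 and 0.37), as the median of all tested genes does (from -0.14 to 0.37).

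Genes of protein synthesis and respiration were lower in part. Of 78 tested cytosolic ribosomal protein genes, 35 were lower, 1 higher and 42 not called (35 lower and 1 higher adjusted over the list alone), with a median of -0.85 against -0.14 for all genes and -0.29 against 0.37 when rescaled over protein-coding genes (camera adjusted p = 3.87e-06, adjusted p = 0.628 with an estimated correlation). RPS29 averaged 170 ± 10.1 TPM after and 1655 ± 345 TPM before differentiation, and RPL39 328 ± 70.6 and 1833 ± 198 TPM (SD, n = 2), genes that share reads with pseudogenes. RPS28 was higher at 33.0 ± 8.43 against 15.8 ± 0.509 TPM (adjusted p = 0.049), a call lost with a pseudocount of 0.1 (adjusted p = 0.0505) and without differentiated replicate 1 or 2 (adjusted p = 0.238 and 0.493). Of 44 tested oxidative phosphorylation genes, 18 were lower, 0 higher and 26 not called (18 lower adjusted over the list alone), with a median of -0.86, and -0.36 when rescaled over protein-coding genes (camera adjusted p = 0.000158, adjusted p = 0.628 with an estimated correlation). ATP5J, a subunit of ATP synthase, averaged 25.2 ± 3.98 and 245 ± 46.7 TPM, and UQCRH 15.8 ± 1.10 and 114 ± 19.0 TPM.

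Glycolysis genes did not move together, with 4 of 21 tested members higher, 4 lower and 13 not called (4 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.94, adjusted p = 0.983 with an estimated correlation). Their median of -0.12 turned to 0.08 after median-of-ratios scaling and 0.43 when rescaled over protein-coding genes, while the median of all tested genes moved likewise from -0.14 to 0.04 and 0.37. The lactate exporter gene SLC16A3 averaged 9.80 ± 1.75 TPM after and 0.295 ± 0.318 TPM before differentiation and the glucose transporter gene SLC2A3 averaged 10.3 ± 0.785 and 2.14 ± 0.0919 TPM. LDHB was lower at 25.3 ± 3.32 against 244 ± 125 TPM (SD, n = 2). SLC2A3 was not called without differentiated replicate 1 or 2 (adjusted p = 0.143 and 0.172).

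Genes tied to the treatment were examined in separate lists. Of 15 tested members of a list drawn up as STAT5 targets (21 in the list), 8 were higher, 2 lower and 5 not called (8 higher and 2 lower adjusted over the list alone). IL-3 activates STAT5, but the list also holds genes such as DUSP6 and EGR1 that are not specific to STAT5. The name STAT5 targets therefore labels the list and does not assign a cause. The STAT5 list had a median log2 difference of 1.10 (camera adjusted p = 0.00251, adjusted p = 0.623 with an estimated correlation). The call of the list was lost among genes of at least 5 TPM (adjusted p = 0.239). The phosphatase gene DUSP6 averaged 66.5 ± 10.7 TPM after and 5.28 ± 2.43 TPM before differentiation (SD, n = 2). ID1 was listed at 7.83 and 11.4 TPM after it and at 0 in both libraries before it. The cyclin gene CCND3 was lower at 8.01 ± 2.28 against 97.8 ± 25.5 TPM. Of 8 tested oestrogen-responsive genes (20 in the list), 4 were higher, 1 lower and 3 not called (4 higher and 2 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.236, adjusted p = 0.756 with an estimated correlation). Its members included CTSD, also a lysosomal protease, at 95.9 ± 26.7 against 4.28 ± 1.47 TPM, IGFBP4 at 19.6 ± 2.21 against 1.99 ± 0.827 TPM, and STC2, lower at 0.31 ± 0.240 against 2.54 ± 0.205 TPM. Without differentiated replicate 1 or 2 the adjusted p for IGFBP4 was 0.0597 and 0.0728, and without replicate 2 that for STC2 was 0.125.

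Of 26 tested unfolded protein and heat shock response genes, 5 were higher, 10 lower and 11 not called (7 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.735, adjusted p = 0.962 with an estimated correlation). The median of -0.02 turned to 0.16 after median-of-ratios scaling and 0.08 after quantile normalization, against 0.04 and -0.08 for all tested genes. The chaperone genes HSPE1 and HSP90AA1 were lower at 8.70 ± 1.51 against 156 ± 32.7 TPM and 53.7 ± 3.82 against 421 ± 122 TPM, and HSPA1A was higher at 8.20 ± 0.311 against 0.315 ± 0.0636 TPM (SD, n = 2). HSPE1 and HSPA1A have near-identical copies and are uncertain.

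Markers of other cell types were mostly below 1 TPM in all 4 libraries. This held for 15 of 20 T cell and NK cell markers, 16 of 18 erythroid and megakaryocyte markers, 17 of 17 mast cell, basophil and eosinophil markers, 17 of 19 dendritic cell markers, 7 of 11 osteoclast markers and 13 of 16 stromal and epithelial markers. The exceptions included TRAC, the T cell receptor alpha constant gene, at 5.22 ± 1.97 TPM after and 80.7 ± 41.3 TPM before differentiation (SD, n = 2, adjusted p = 3.24e-05), and ZAP70 at 0.395 ± 0.0919 against 2.08 ± 0.559 TPM. PPBP, a platelet chemokine gene, was listed at 22.6 and 23.7 TPM after and at 0.09 and 0 TPM before differentiation, and ITGA2B at 1.11 TPM in undifferentiated replicate 2 and 0 elsewhere. TPSAB1 and KIT reached at most 0.36 and 0.39 TPM in any library. The dendritic cell gene LAMP3 was lower at 0.17 ± 0.0141 against 6.41 ± 1.57 TPM, and CLEC10A was listed at 1.06 and 1.68 TPM after and at 0 in both libraries before differentiation. OSCAR averaged 2.50 ± 0.856 and 0.035 ± 0.00707 TPM and DCSTAMP was listed at 2.32 and 2.38 TPM after and at 0 in both libraries before it. PECAM1 averaged 6.86 ± 0.502 and 0.715 ± 0.262 TPM. PDGFRB was lower at 0.64 ± 0.325 against 3.62 ± 1.95 TPM. Left out in turn, differentiated replicates 1 and 2 gave an adjusted p of 0.131 and 0.0882 for ZAP70, 0.0673 and 0.0662 for LAMP3, and 0.158 and 0.312 for PDGFRB.

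Of 15 mitochondrially encoded genes, 1 was higher, 4 lower and 10 not called, with a median of -0.18 that turned to 0.04 after median-of-ratios scaling, against -0.14 and 0.04 for all tested genes. MT-RNR1 averaged 65810 ± 7318 TPM after and 44540 ± 18070 TPM before differentiation and was not called (adjusted p = 0.101) except with robust eBayes (adjusted p = 0.031). MT-RNR2 averaged 55990 ± 2780 and 32850 ± 3731 TPM (SD, n = 2, adjusted p = 0.0187). The call of MT-RNR2 was lost after median-of-ratios scaling (adjusted p = 0.152), with eBayes without a trend (adjusted p = 0.08) and with any single library left out. It was also lost under quantile normalization. That setting gives genes of equal rank the same value in every library, so it cannot decide on a gene this abundant. Of 11 tested small structural RNAs, 5 were called higher, 2 lower and 4 not called, counts that include RNU5A-1 and RNU1-1 with their zeros in a whole stage, and RN7SL1 averaged 61870 ± 1101 and 59350 ± 15680 TPM (adjusted p = 0.812). Of 15 housekeeping genes, 1 was higher, 2 lower and 12 not called, with a median of -0.65, and -0.12 when rescaled over protein-coding genes, against -0.14 and 0.37 for all tested genes. ACTB averaged 372 ± 24.2 and 199 ± 25.3 TPM (adjusted p = 0.0403), and GAPDH 289 ± 65.1 and 492 ± 260 TPM (adjusted p = 0.191). ACTB was not called with a pseudocount of 5 (adjusted p = 0.0673) or without differentiated replicate 1, differentiated replicate 2 or undifferentiated replicate 1 (adjusted p = 0.249, 0.319 and 0.0541), and GAPDH was called lower without undifferentiated replicate 2 (adjusted p = 0.0221) and with the GC trend removed (adjusted p = 0.0136).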

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

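The alternatives that rescale over protein-coding genes, remove GC or length trends, or estimate the correlation after median-of-ratios scaling were chosen after the data had been seen. No gene called as reported was called in the opposite direction under any alternative. The total of 4216 called genes became 1260 without a filter on low values, 2436 among genes of at least 5 TPM, 1305 in a test against a log2 fold change of 1, and 6330 over protein-coding genes with median-of-ratios scaling, and it ranged from 1271 to 5652 with single libraries left out, where the remaining library of a stage is assumed to vary like the other stage. The stricter filter and the test against a fold change lower the count by construction, and the cause of the other moves was not tested. Genes called higher numbered 687 without a filter, 1016 at 5 TPM, 698 against a fold change, 2915 after median-of-ratios scaling, 3616 after rescaling without abundant RNAs, 4102 over protein-coding genes and 3339 with median-of-ratios scaling of these, and 934 to 2714 with single libraries left out. Genes called lower numbered 573 without a filter, 1420 at 5 TPM and 607 against a fold change, and 337 to 3818 with single libraries left out. Genes with a log2 difference of at least 1 numbered 1790 with a pseudocount of 5, 1260 without a filter, 2355 at 5 TPM, 6031 after rescaling without abundant RNAs and 1305 against a fold change, and 1183 to 4550 with single libraries left out.

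Of the 19 called lists, 18 kept their call with each library left out in turn. Cytosolic nucleic acid sensing lost it without undifferentiated replicate 1 (adjusted p from 0.0107 to 0.0575 over the left-out libraries), without a filter (0.0808), at 5 TPM (0.173), after rescaling without abundant RNAs (0.0577) or over protein-coding genes (0.0568), with GC (0.0582) or length (0.0571) trends removed and by fry (0.159), for causes that were not tested. At 5 TPM the B cell transcription factors (0.086) and STAT5 targets (0.239) also lost their call, and fry did not call the B cell transcription factors or oxidative phosphorylation (0.0792 each), ribosomal proteins or STAT5 targets (0.0912 each). Without a filter, B cell surface genes (0.0192) and cholesterol synthesis (0.00184) gained a call. With an estimated correlation, which leaves camera 2 degrees of freedom, the adjusted p was 0.401 for pre-B genes, 0.534 for Toll-like receptors, 0.71 for cytosolic sensing, 0.628 for B cell transcription factors, ribosomal proteins and oxidative phosphorylation, 0.623 for STAT5 targets and 0.397 for the other 12 called lists. After median-of-ratios scaling it was 0.277 for B cell transcription factors and STAT5 targets, 0.129 for Toll-like receptors and nucleases, 0.297 for cytosolic sensing, 0.201 for cytokines, 0.316 for histones, 0.516 for ribosomal proteins, 0.376 for oxidative phosphorylation and 0.127 for the other called lists.

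The stages share replicate numbers, but over 2 pairs the deviations of same-numbered libraries correlated across genes at r = -0.024 (Spearman 0.05), so they were treated as sharing only a number, although 2 pairs cannot exclude a pairing, and along GC replicate 1 minus 2 had spans of the same sign in both stages (-0.158 and -0.585). With the replicate number as a block, 3766 genes were called, 1730 higher and 2036 lower, and of the list calls only that of cytosolic nucleic acid sensing changed (adjusted p = 0.0619), together with those of 2 named genes, RPS28 (0.131) and ACTB (0.129). The prior degrees of freedom of the block fit were infinite. Each gene's variance in it therefore came from the mean-variance trend alone and not from the gene's own spread. Of 99 named gene symbols, 22 lost their call without differentiated replicate 1 and 24 without differentiated replicate 2, 21 of them in both fits, and 19 lost it without a filter and 19 in the test against a fold change. Those lost in both of the latter were CEBPA, TLR8, NFIL3, RNASEH2B, ERI1, DFNA5, HERC5, HLA-C, HMGCS1, RPS28, STC2, ZAP70, CLEC10A, PDGFRB, MT-RNR2, RN7SK and ACTB, with FABP5 and OSCAR lost only without a filter and RNASET2 and SLC2A3 only against a fold change. TPM holds no depth, so what sequencing depth limits could not be assessed.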

Other observations

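The tests on the GC span, on the balance of directions and on residual undifferentiated cells were chosen only after the result was seen, as were the complement and iron lists and the genes named from them. Removal of GC or length trends and rescaling over protein-coding genes were also chosen after the data had been seen. No set test is given for the complement and iron lists, since they were drawn up after such genes had been seen to differ. Of 12 tested complement components, receptors and regulators (19 in the list), 10 were higher and 0 lower in differentiated cells, and CD46 and CD59 were not called. Apart from CD55, the 10 averaged below 1 TPM before differentiation and passed the filter through the differentiated libraries. The counts therefore depend on this filter and on how the list was chosen. Of the 10, 3 (C3AR1, C5AR1 and VSIG4) are also in the list of macrophage receptors. The C1q chains, which start the classical pathway, were listed at 0 in both undifferentiated libraries and averaged 28.5 ± 5.57 TPM (C1QA), 18.1 ± 2.95 TPM (C1QB) and 49.3 ± 8.97 TPM (C1QC) after differentiation (SD, n = 2). C3 averaged 35.6 ± 2.17 TPM against 0.005 ± 0.00707 TPM before differentiation, and the complement receptor gene VSIG4 averaged 76.5 ± 13.9 TPM and was listed at 0 before it.

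Of 15 tested iron and haem handling genes (18 in the list), 9 were higher, 1 lower and 5 not called, and 1 of the 9, CD163, is also in the list of macrophage receptors. The ferritin heavy chain gene FTH1 averaged 4061 ± 550 TPM after and 96.5 ± 13.6 TPM before differentiation, and the light chain gene FTL 4438 ± 745 and 855 ± 118 TPM (SD, n = 2). Both have many processed pseudogenes, so their values are uncertain. HMOX1, which degrades haem, averaged 101 ± 9 and 0.04 ± 0.0566 TPM, the haemoglobin scavenger gene CD163 28.3 ± 0.0283 TPM with 0 before differentiation, and the iron exporter gene SLC40A1 7.78 ± 0.891 TPM with 0 before it. The transferrin receptor gene TFRC was lower at 3.40 ± 0.905 against 23.2 ± 8.13 TPM.

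The first pattern is that differences between stages rose with GC content, from a median log2 difference of -0.51 in the lowest eighth of protein-coding genes by GC to 0.35 in the highest, a span of 0.857. The undifferentiated libraries, which share a stage, differed along GC by a span of 0.585 in size (-0.585 for replicate 1 minus 2), and the differentiated libraries by -0.158 in the same direction, so a GC bias that differs between libraries may contribute. As the whole cause of the list calls it is argued against, because 18 of the 19 called lists stayed called in the same direction with the GC trend removed. The list that lost its call, cytosolic nucleic acid sensing, went from a median of 0.53 ± 1.32 (SD over members) to 0.70 ± 1.29 and from an adjusted p of 0.0331 to 0.0582. The median of all tested genes rose likewise, from -0.14 to 0.01. Camera compares a list with the other genes, so the members' median does not show why the call ended, which was not tested. A difference in base composition between the transcripts of the stages stays open and was not tested.

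A second pattern is the excess of lower over higher calls, together with lower ribosomal protein and oxidative phosphorylation lists. Whether scaling TPM over abundant structural RNAs gave the excess cannot be told apart, because a rescaling shifts all genes of a library alike and the largest move in the share of higher calls, 20.8 percentage points, came where the tested genes changed as well. With the tested genes unchanged, median-of-ratios scaling turned the excess (52.4% of calls higher) and quantile normalization kept it (46.3%), against 44.8% as deposited. At unchanged scaling and over the same genes the excess turned without undifferentiated replicate 1 (56.4% of calls higher) and without differentiated replicate 1 or 2 (73.4% and 73.5%), and it grew without undifferentiated replicate 2 (32.4%). Transcript length bias as the whole cause of the calls of the lower lists by camera with the preset correlation is argued against. With the length trend removed, the larger of their camera adjusted p-values was 0.000806. This holds for those calls alone, since neither list was called with an estimated correlation (adjusted p = 0.628 each) or by fry (0.0912 and 0.0792). What length trend remained after the removal was not measured. Whether total RNA per cell changed stays open, because TPM holds no absolute amounts.

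The remaining pattern is that B cell transcripts remained at different levels after differentiation. For tested list members of at least 10 TPM in undifferentiated cells, the level remaining had a median of 2.95% over 10 pre-B genes, all called lower, and 13.6% over 20 B cell genes, or 10.9% over the 15 called lower (2.56% for CD24 to 45.0% for RUNX1) without TCF4, IKZF1, BCL6, ID3 and CD9 (47.2% to 253%). If residual cells with the profile of the undifferentiated libraries were the whole source, B cell genes would stay under a ceiling of 4.24%. This ceiling is the median over pre-B genes of the highest share any pairing of libraries gives. Of the 15 B cell genes called lower, 10 exceeded it in every pairing, including CD79A at 11.4% and CD79B at 15.7%. Of all 20, 15 exceeded it, but ID3 and CD9 were called higher and BCL6 stood at 134%, so they were bound to pass. Some of the B cell genes above it, such as RUNX1, BLNK and PIK3AP1, are also expressed in myeloid cells. The pre-B list includes repair genes used in all cells (19.4% to 32.5% remaining for PRKDC, XRCC6 and XRCC5), which exceeded the ceiling as well. A scaling difference between libraries would move pre-B and B cell genes alike. Whether residual cells keep the undifferentiated profile under treatment was not tested. Unequal transcription or decay of these transcripts within the differentiated cells is a candidate explanation that was not tested.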
